A study of Mus musculus with 2 samples.

How the data were processed

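RNA from 1 immunopurified and 1 input library of mouse subcortical brain was measured by sequencing. The immunopurified library was made from polysomes captured with anti-EGFP antibodies on magnetic beads, per the labels' protocol. The labels do not say whether both libraries came from the same animals or how many animals were pooled. The deposited values are counts of reads per gene symbol, not normalised, made with STAR 2.0.0e and HTSeq (version not given) on the mm10 build, per the submitters' processing notes. The notes state neither the role nor the order of these tools, and the gene annotation, the strand setting and any filters are not given in the sources used here. The 5 summary rows that HTSeq appends, and a row named unknown with 1 and 2 counts, name no gene and were left out of the totals.

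In the immunopurified and input libraries respectively, 10.2% and 14.1% of all rows were reads in no feature, 1.64% and 9.64% were ambiguous between features, and 41.5% and 29.6% were alignments at more than 1 place. Genes that overlap or share sequence with others therefore lost reads, and those known to do so are named as uncertain. The most abundant feature took 8.13% of the immunopurified counts (the ribosomal RNA precursor Rn45s, at 3.68% in the input) and 13.5% of the input counts (a feature named by a clone accession). The top 10 features took 13.1% and 25.5%. Of 32531 features, 23113 matched a GENCODE M21 symbol (GRCm38, the assembly of mm10), 770 matched through a synonym, 8190 are named only by a clone accession and 458 others had no match. Clone-named features held 1.54% of the immunopurified and 16.6% of the input counts. The files carry no coordinates, so those printed are from GENCODE M21. The files used hold no feature with the mt- prefix that names genes of the mitochondrial genome. Whether clone-named features hold reads of that genome was not tested. The list members C1s, Drd1a, Hba-a1, Hbb-b1, Hbb-bt and Trbc2 have no row under those symbols.

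CPM was computed over the total counted on genes, 35443797 and 37242869. Genes with a mean CPM of at least 1 over both libraries were measured, 14710 in all. A gene below 1 CPM in 1 library passes only through the other, so at low levels this filter favours large ratios. Each ratio has an exact 95% interval (Clopper-Pearson, conditional on the gene's summed count). A count of 0 was set to a floor of 3 counts, 0.0846 CPM in the immunopurified and 0.0806 CPM in the input library. A gene counted as higher or lower at a ratio of at least 4 or at most 0.25, a rule of size and not a test. With 1 library per group neither edgeR nor DESeq2 could estimate the spread between libraries, so their tests were not run and they gave scaling factors only. List members counted as higher or lower at 2-fold. Each list has the median log2 ratio over measured members, an order-statistic interval over genes, and its percentile among 10000 random lists of the same size matched on mean expression in 20 bins, which describes these libraries only.

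The design, the alternatives, 30 lists of marker and pathway genes and the rule for named genes were chosen before the data were examined. The rule names Cfh and Rpl10a, 2 to 4 measured members of each list with the highest mean CPM or the largest ratio either way, and the 25 highest and 25 lowest genes ranked by the interval bound nearest 1. A few further list members are printed to show the range of a list, and genes of families chosen after the data were seen are named as such. Ribosomal and respiratory groups were defined by symbol (Rpl and Rps, Mrpl and Mrps, Nduf, Uqcr, Cox and Atp5), leaving out Rpl10a. Several microglia genes are also members of other lists: Ctss, Hexb and Laptm5 of the lysosome list, the C1q genes and Itgam of complement, Sall1, Spi1 and Irf8 of the transcription factors, and P2ry12 and P2ry13 of purinergic signalling. Alternatives covered scaling (edgeR TMM, DESeq2 size factors, upper quartile, totals without the 10 most abundant genes), filters, an added CPM of 1, other sizes of the fold rule and random lists matched on input CPM. A scaling by the total over symbols found in GENCODE M21 was added after the data were seen.

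The calculation was tested on simulated counts for 14668 genes of this comparison, with counting error only. In it, 100 genes were raised and 100 lowered 8-fold. All of these that still reached the measured level in the simulated counts were recovered at 4-fold. Any lowered gene that fell below that level was left out of the score. Among measured genes 0 unchanged genes were called, and 95.1% of intervals held the true ratio. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.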

Results

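Translating ribosome affinity purification (TRAP) followed by RNA sequencing was applied to subcortical brain tissue of adult mice of the Cfh-EGFP/Rpl10a line (NIDA092), on a C57BL/6J background. By its name the line carries an EGFP fusion of ribosomal protein L10a linked to Cfh, the complement factor H gene. The series description gives microglia, the resident macrophages of the brain, as the cells profiled. The series holds 1 immunopurified library, made from RNA bound to ribosomes captured with anti-EGFP antibodies, and 1 input library from the same kind of tissue. The immunopurified library had 35443797 reads counted on genes, over 19338 features with at least 1 count. The input library had 37242869, over 20908 features. With 1 library per group no difference has a replicate check, and neither a test nor an SE is given. Ratios are CPM (counts scaled to each library's total on genes) in the immunopurified library over CPM in the input, with exact 95% counting intervals. These intervals address counting error between these 2 libraries only. PCR reads without molecular identifiers are not independent molecules, so the intervals can be too narrow even for that error. Of all features, 14710 had a mean of at least 1 CPM and are called measured.

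The targeted gene was read before all others, since it checks the labels. Cfh, which encodes an inhibitor of the alternative complement pathway, stood at 159 CPM in the immunopurified library and at 5.40 CPM in the input (5649 and 201 counts), 29.5-fold higher (25.7 to 34.2). Reads of the transgene may count under Cfh, and whether they did was not tested. Cfh lies on chromosome 1 from 140084708 to 140183764 on the minus strand of GRCm38 (mm10). None of the measured genes next to it was as high: Kcnt2, 62.4 kb away, had a ratio of 0.423 (0.367 to 0.488), Zbtb41 of 0.748 and Dennd1b of 0.831. Rpl10a, the gene of the tagged protein, stood at 2.91 and 4.08 CPM (103 and 152 counts), a ratio of 0.712 (0.549 to 0.920). It lies on chromosome 17 from 28328471 to 28331033 on the plus strand. All 602 words of 50 bases in the Rpl10a coding sequence also occur in transcripts of annotated pseudogenes, and its exons overlap another gene, so its count is uncertain.

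The comparison of the immunopurified library with the input asks which transcripts are attached to tagged ribosomes more than their share of the tissue RNA. Microglial transcripts led the higher side. All 30 genes of the microglia list were at least 4-fold higher, 28 of them at least 16-fold, with a median of 80.7-fold (68.3 to 95.8 over genes). Together the 30 genes took 14295 CPM in the immunopurified library and 214 CPM in the input. The median lay above those of all 10000 random lists of matched expression. C1qb, a subunit of complement C1q, stood at 1317 CPM against 9.10 CPM, 145-fold higher (130 to 161). The surface protein Tmem119 was 127-fold higher (109 to 149), the purinergic receptor P2ry12 90.4-fold (82.0 to 99.8), the fractalkine receptor Cx3cr1 78.6-fold (70.7 to 87.6) and the colony-stimulating factor receptor Csf1r 71.9-fold (65.2 to 79.4). The smallest ratios of the list were those of the phagocytic receptor Mertk at 7.32-fold, the transcription factor Sall1 at 13.6-fold and Tgfbr1, a TGF-beta receptor, at 18.5-fold. Their input levels were 12.9, 31.2 and 16.9 CPM.

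**Figure D1:**
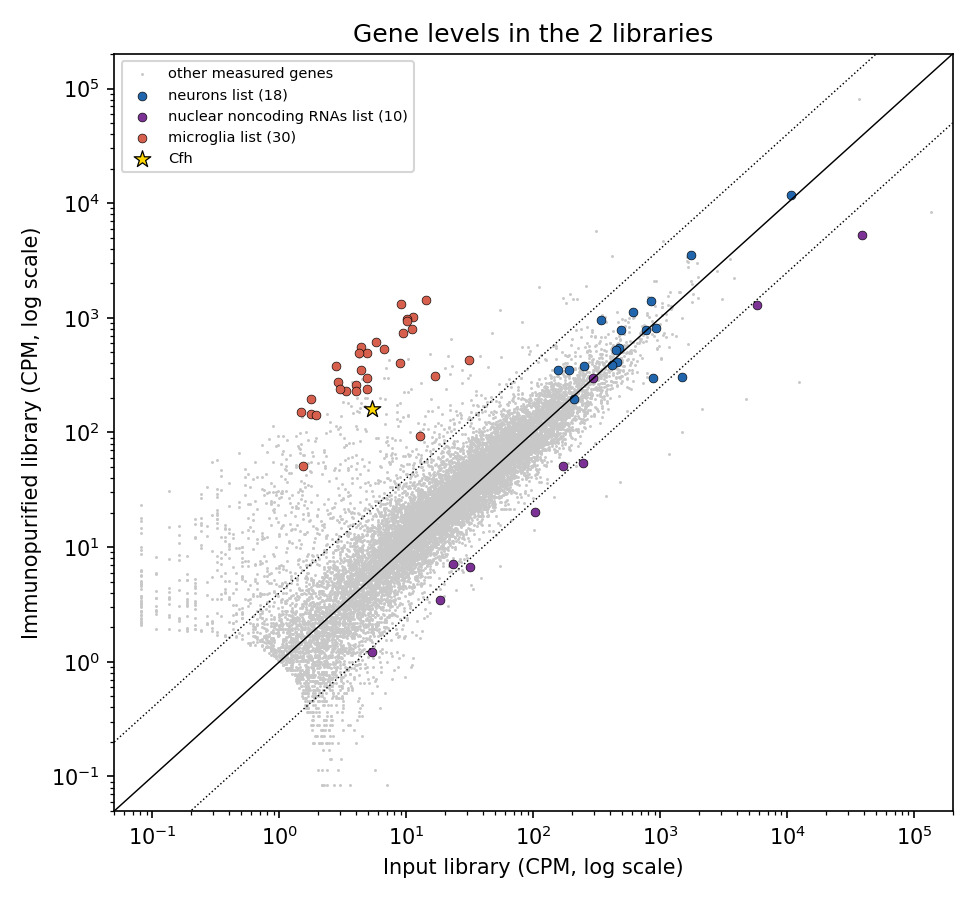
Each point is a measured gene, with its CPM in the input library on the horizontal axis and in the immunopurified library on the vertical axis, both on log scales; the solid line marks equal CPM and the dotted lines a 4-fold difference. The 30 microglia genes (red) and Cfh (star, 159 against 5.40 CPM) lie above the upper dotted line, neuron genes (blue) lie around the solid line, and 9 of the 10 nuclear noncoding RNAs (purple) lie below it by at least 2-fold.

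Across the transcriptome, 896 genes were at least 4-fold higher in the immunopurified library, 843 of them protein-coding, and 286 were at least 4-fold lower. Scaling moved this split: with upper-quartile scaling it was 757 higher and 449 lower, and with totals that leave out the 10 most abundant genes of either library it was 817 and 474. The filter moved it more: with no filter on low counts it was 1263 higher and 1269 lower, and at a mean of at least 5 CPM 638 and 59. Of all measured genes 382 were at least 16-fold and 91 at least 64-fold higher, while 11314 genes (76.9%) lay within 2-fold. The 4-fold higher genes took 8.87% of the immunopurified counts (8.86% to 8.88%, Clopper-Pearson) and 0.839% of the input counts (0.836% to 0.842%). These genes were picked by their ratio in the same libraries, so a gap between the shares was given in advance. The intervals leave out that choice and the scaling.

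Of the 25 genes ranked highest by the lower interval bound, 13 belong to the microglia list and the others to no list, with ratios from 90.4 to 314. The leading gene was Gpr160, an orphan G protein-coupled receptor on none of the lists, with 634 immunopurified counts and 0 in the input. It was at least 222-fold higher against a floor of 3 input counts, and the lower bound of its counting interval was 180.1. Aif1, which encodes the microglial marker protein Iba1, was 136-fold higher. The lectin Siglece was 229-fold higher (97.7 to 706), a count made uncertain by related Siglec genes, and Ptafr, the receptor for platelet-activating factor, 291-fold (99.3 to 1414, on 3 input counts). Samsn1 was 189-fold higher, the chemokine Ccl9 179-fold, Tmem173, which encodes the DNA-sensing adaptor STING, 138-fold, Fermt3 134-fold, Bin2 108-fold, Hhex 107-fold and Hcls1 106-fold. A pair of neighbouring crystallin genes, known for their products in the eye lens, was also among them. Crybb1 (chromosome 5, 112255815 to 112269585) stood at 113 CPM against 0.886 CPM, 128-fold higher (90.9 to 186). Cryba4 (chromosome 5, 112246493 to 112252518) was 314-fold higher (86.6 to 2600, on 2 input counts). Exons of P2ry12 and Fermt3 overlap those of other genes, so reads there could be lost or shared.

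Genes of innate sensing were higher as a group. All 13 measured toll-like receptor genes and partners were at least 2-fold higher, with a median of 31.4-fold (log2 ratio 4.97). Several have few counts, and with 1 CPM added to both libraries the median log2 ratio was 2.99. Cd14, the lipopolysaccharide co-receptor, was 56.2-fold higher, the nucleic acid sensors Tlr7 and Tlr13 46.0-fold and 41.3-fold, and Tlr3 3.20-fold. Among myeloid transcription factors 15 of 16 were at least 2-fold higher, with a median of 12.5-fold. Spi1, which encodes the lineage factor PU.1, was 103-fold higher, Irf8 73.1-fold, Ikzf1 58.5-fold and Mafb 31.6-fold, and Bhlhe41 lay at 1.88-fold. The list of cytokines and chemokines had 11 measured members, 6 of them at least 2-fold higher. These included the inflammasome sensor Nlrp3 at 50.3-fold, Ccl12 at 44.3-fold, Tgfb1 at 42.0-fold and Il1a at 21.6-fold. Tnf and Il1b stayed below the measured level, at 0.169 and 0.451 CPM in the immunopurified library.

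The complement list split. Of 18 measured members 9 were at least 2-fold higher, 2 lower and 7 within 2-fold, with a median of 1.84-fold (log2 ratio 0.88). Among members of at least 5 CPM the median log2 ratio was 5.003. That filter is on the mean of both libraries, so it favours higher genes. Itgb2 (63.9 against 1.21 CPM) and C5ar1 (24.4 against 0.779 CPM) pass it only through the immunopurified library. The higher genes were Cfh, the C1q subunits, the integrin chains Itgb2 (52.9-fold) and Itgam (65.1-fold), the anaphylatoxin receptors C3ar1 (32.8-fold) and C5ar1 (31.3-fold), and Cr1l (2.10-fold). The central component C3 had a ratio of 1.37 (0.931 to 2.03) and C4b of 1.25 (0.813 to 1.93). Factor B, Cfb, was 2.30-fold lower and properdin, Cfp, 2.68-fold lower.

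Lysosomal and antigen presentation genes were also higher. Of 22 lysosomal genes 21 were at least 2-fold higher, with a median of 8.16-fold. The protease Ctss was 99.5-fold higher (91.3 to 109), Cd68 48.7-fold, Ctsh 44.4-fold and progranulin, Grn, 14.7-fold, whereas Gba lay at 1.53-fold. Of 15 antigen presentation genes 14 were at least 2-fold higher, with a median of 6.35-fold (log2 ratio 2.67, or 2.03 with 1 CPM added). The co-stimulatory gene Cd86 was 85.1-fold higher, B2m, the light chain of MHC class I, 21.2-fold at 1168 CPM, and H2-K1 7.78-fold. Ciita, the master regulator of MHC class II, had a ratio of 0.525. Genes of the H2 complex share sequence with close relatives, and their counts are uncertain. The list for purinergic signalling had 7 of 12 members at least 2-fold higher, with a median log2 ratio of 1.76, or 0.87 with no filter on low counts. The higher genes included P2ry6 (51.8-fold), Adora3 (21.3-fold) and the ATP-degrading enzyme Entpd1 (13.9-fold), whereas P2rx5 was 3.43-fold lower. Among interferon response genes 7 of 11 were at least 2-fold higher, with a median of 2.14-fold, which was under 2-fold with 3 of the 5 other scalings and with 1 CPM added. Bst2 was 25.5-fold and Irf9 6.81-fold higher, and Ifit2 had a ratio of 0.965.

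Genes that mark disease-associated microglia did not share 1 direction. Of 16 measured members 8 were at least 2-fold higher, 2 lower and 6 within 2-fold, with a median of 2.04-fold, which was under 2-fold with each other scaling. Ccl6 was 95.8-fold higher, the protease Ctsd 16.6-fold at 1842 CPM, and the tetraspanin Cd9 8.67-fold. Cst7 and Clec7a had 109 and 78 immunopurified counts, against 1 and 2 in the input. The lipid carrier Apoe lay at 1.88-fold and Spp1 at 1.27-fold, Igf1 was 2.15-fold lower and Gpnmb 2.56-fold lower.

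Markers of related blood and border cells gave smaller values. Of 12 markers of border-associated macrophages 7 were measured, 6 of them at least 2-fold higher, with a median of 5.31-fold (0.580 to 19.2 over these genes). The median log2 ratio of 2.41 became 1.52 with 1 CPM added and 4.26 at a minimum of 5 CPM, which 1 gene reaches. Stab1 was 19.2-fold higher at 18.1 CPM, Cbr2 7.39-fold and Pf4 6.15-fold at 3.47 CPM, and Cd163 had a ratio of 0.580. Against random lists matched on input CPM, in place of mean CPM, this median lay at the 84.6 percentile. Random lists hold measured genes only, and a gene below 1 CPM in the input is measured only through the immunopurified library. The draw for Lyve1, Pf4, Cbr2 and Stab1, all below 1 CPM in the input, therefore favours higher genes and lowers this percentile. None of the blood leukocyte markers was measured, and all of them together had 94 counts in the immunopurified library and 48 in the input. Of 4 measured red blood cell genes 2 were at least 2-fold lower, including the erythroid enzyme Alas2 at 4.58-fold lower and Hbb-b2 at 2.91-fold lower. Globin genes are near-identical copies, and their counts are uncertain.

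Markers of neurons, macroglia and vascular cells lay close to a ratio of 1. Over 12 lists and 155 measured members, 134 lay within 2-fold, 12 were higher and 9 lower, and the median ratio was 1.02. List medians ran from 0.760 (GABAergic and striatal neurons) to 1.47 (vascular and leptomeningeal fibroblasts). The synaptic gene Snap25 stood at 11707 CPM in the immunopurified library, with a ratio of 1.09 (1.08 to 1.09). The astrocyte glutamate transporter Slc1a2 had a ratio of 0.612 and water channel Aqp4 of 0.745. The myelin genes Plp1 and Mbp had 0.584 and 0.679, the precursor gene Pdgfra 1.23, the hypocretin gene Hcrt 0.947 and Ttr of the choroid plexus 0.944. Of 15 endothelial genes 12 lay within 2-fold, among them the most abundant, Slc2a1 (1.54), and Cldn5 (1.10) and Flt1 (0.918). The largest departures were the endothelial adhesion gene Pecam1 at 4.75-fold higher and the neuronal noncoding RNA Snhg11 at 4.80-fold lower. Other members beyond 2-fold included Col1a1 and Igfbp2 of fibroblasts, at ratios of 3.57 and 3.48, and Cdh5 and Kdr of endothelial cells, at 2.98 and 2.40. The lower side included Matn4 and Vcan of the precursors, at 0.273 and 0.358. It also held the abundant neuronal gene Map2 at 0.338 (297 against 879 CPM) and the oligodendrocyte gene Mobp at 0.389 (306 against 787 CPM). Medians of the other lists were 1.16 for neurons, 0.869 for glutamatergic and thalamic neurons, 1.25 for hypothalamic and monoaminergic neurons, 0.824 for astrocytes, 0.848 for oligodendrocytes, 1.02 for their precursors, 1.10 for endothelial cells, 1.06 for pericytes and smooth muscle, 0.920 for ependymal cells and 0.977 for choroid plexus epithelium. Against random lists of matched expression the medians of GABAergic and striatal neurons, astrocytes, oligodendrocytes, and glutamatergic and thalamic neurons lay at the 0.24, 1.08, 3.20 and 4.57 percentiles, and that of fibroblasts at 95.5. Matched on input CPM, these 5 lists lay at the 0.64, 3.69, 13.8, 13.2 and 89.5 percentiles. The mean and the median of the log2 ratio differed in sign for the precursors and the choroid plexus.

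**Figure D2:**
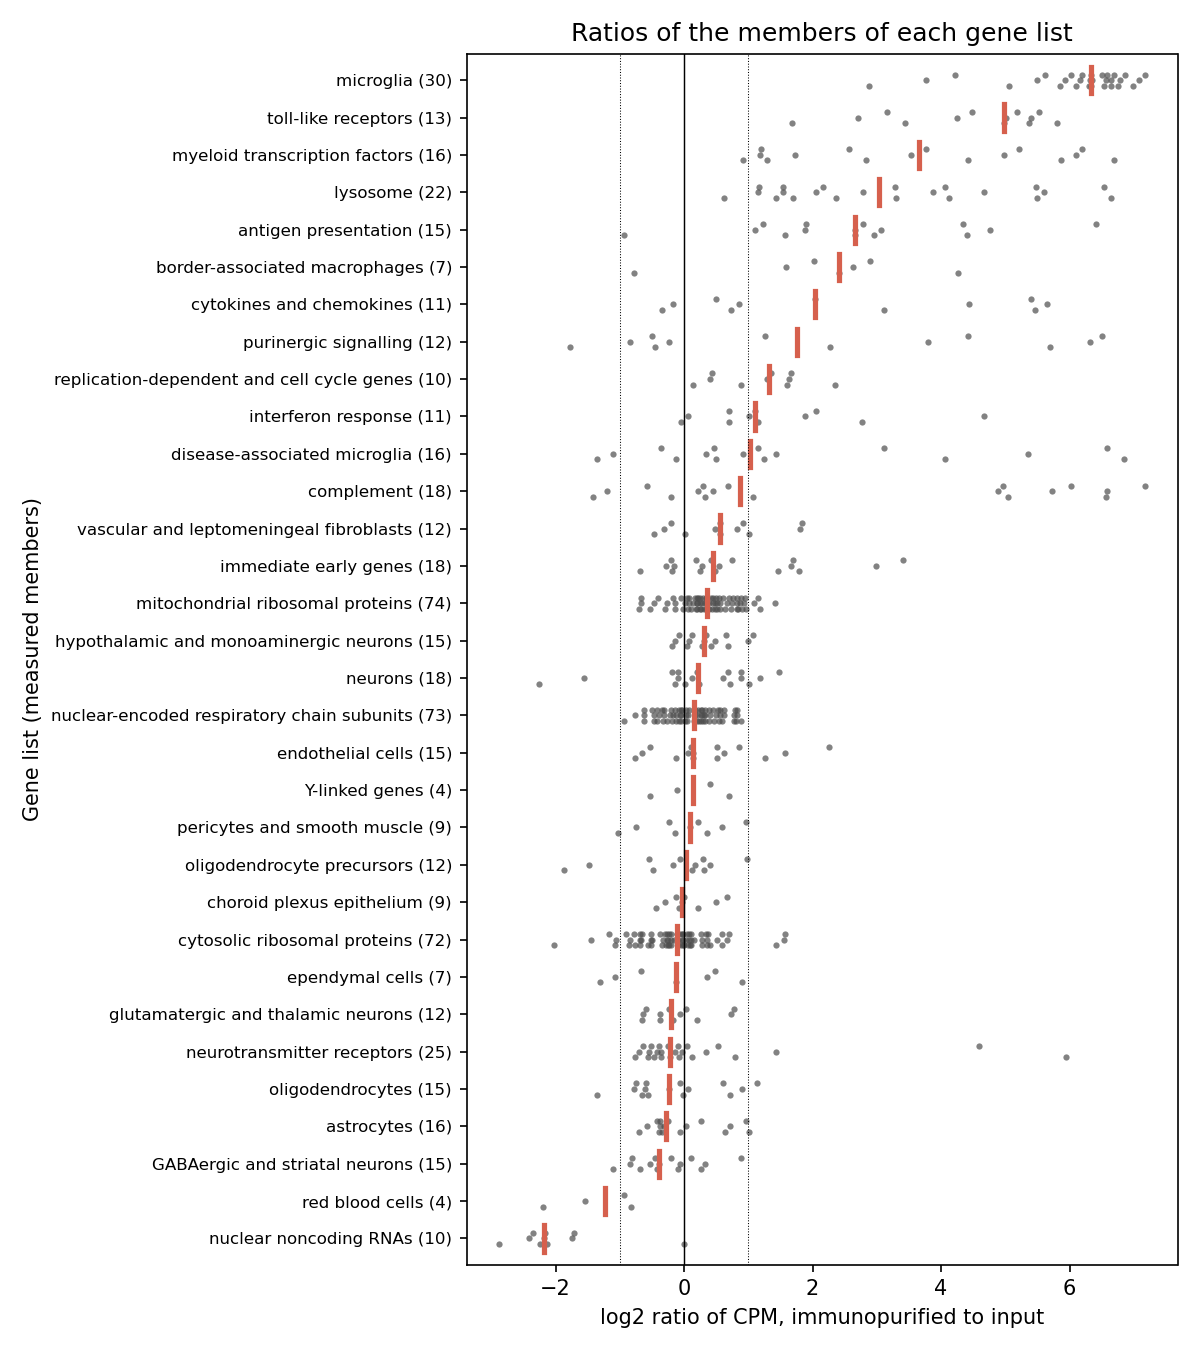
Each row is a gene list with its number of measured members, each grey point is the log2 ratio of immunopurified to input CPM of 1 member, and each red bar is the list's median; dotted lines mark 2-fold. The microglia list has the highest median (6.34), the lists of other brain and vascular cells have medians from -0.40 to 0.55, and nuclear noncoding RNAs have the lowest (-2.18).

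Neurotransmitter receptors followed the neuronal lists, with 22 of 25 within 2-fold and a median ratio of 0.862; the mean log2 ratio differed in sign from the median. The exceptions were the beta-adrenergic receptors Adrb2 (24.0-fold higher, 23.2 against 0.967 CPM) and Adrb1 (2.70-fold) and the cannabinoid receptor Cnr2 (61.3-fold, 20.6 to 300, on 3 input counts). The neuronal cannabinoid receptor Cnr1 had a ratio of 0.614. Among immediate early genes 6 of 18 were at least 2-fold higher, led by Atf3 (10.6-fold) and Zfp36 (7.95-fold), while Fos had a ratio of 1.34 and Egr1 of 0.898. Of 10 measured cell cycle genes 6 were at least 2-fold higher, with a median log2 ratio of 1.32. It was under 2-fold with upper-quartile scaling (0.997) and with 1 CPM added (0.80). Matched on input CPM, the median of 1.32 lay at the 76.9 percentile of random lists. For any member below 1 CPM in the input such lists favour higher genes, as for border-associated macrophages. The replication factor Mcm2 was 5.07-fold and Pcna 2.45-fold higher, and the proliferation marker Mki67 had a ratio of 1.10. The 4 Y-linked genes lay within 2-fold, with a median ratio of 1.10.

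Noncoding RNAs of the nucleus were lower. Of 10 measured members 9 were at least 2-fold lower, with a median of 4.52-fold lower, below all random lists. Malat1 was 7.37-fold lower, Xist 5.33-fold, Snhg14 5.09-fold, Miat 4.54-fold and Meg3 4.50-fold, and Peg13 stood at 297 CPM in both libraries. Of the 286 genes at least 4-fold lower, 178 are features named only by a clone accession and 47 are protein-coding. Among the 25 lowest genes by interval bound, 21 are such clone features, whose genes of origin were not determined. The others are Sorbs2os (2 and 81 counts, 38.5-fold lower), 4933428G20Rik (19.6-fold lower), E330033B04Rik (13.4-fold lower) and Gdap10, a noncoding RNA gene on chromosome 12 from 32821872 to 32826904 (11.8-fold lower). Exons of Sorbs2os and 4933428G20Rik overlap other genes, and without a stated strand setting their reads cannot be told from those of their partners.

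Most housekeeping genes of protein synthesis and respiration lay within 2-fold. Of 72 cytosolic ribosomal protein genes 64 lay within 2-fold, 3 were higher and 5 lower, from Rpl9 at a ratio of 0.246 to Rps27l at 2.97. Their median ratio was 0.929, at the 1.48 percentile of random lists (2.32 matched on input CPM). Their many pseudogenes make these counts uncertain. Of 74 mitochondrial ribosomal protein genes 70 lay within 2-fold (median ratio 1.27), as did all 73 nuclear-encoded respiratory chain genes (median ratio 1.11). Other scalings shift every log2 ratio down, by 0.06 to 0.29, so list medians from 1.02 to 1.16 crossed to the lower side with upper-quartile scaling. The medians of the microglia and nuclear noncoding lists kept their direction under every scaling. With 1 library per group, these values describe this pair of libraries.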

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

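Alignments at more than 1 place, which enter none of the gene counts, made up 41.5% of all rows of the immunopurified library and 29.6% of those of the input (31517798 and 23591101), and they stand out as signal outside the measurement that the report uses. Rn45s, the ribosomal RNA precursor, was also higher among the counted features, at 8.13% against 3.68%.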

How the results depend on the processing

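The scaling by GENCODE M21 symbols was chosen after the data were seen. Cfh, the microglia median and the other list medians beyond 2-fold kept their direction under every alternative run on them, but not always their size. Of 12 such lists, 11 remained beyond 2-fold with TMM or DESeq2 size factors, 10 without the 10 most abundant genes or with GENCODE M21 symbols, 9 with the upper quartile, 11 with no filter, 10 at 5 CPM (where complement was added) and 8 with 1 CPM added. Disease-associated microglia, interferon response, red blood cells and cell cycle genes were the ones lost with 1 CPM added, at median log2 ratios of 0.95, 0.98, -0.96 and 0.80. That setting also lowered the toll-like receptor median from 4.97 to 2.99, as it does by construction for genes of few counts. The alternative scalings shift every log2 ratio by 1 constant: -0.06 with TMM, -0.07 with DESeq2 size factors, -0.29 with the upper quartile, -0.22 without the 10 most abundant genes and -0.18 with GENCODE M21 symbols. They move the median over measured genes from 0.14 to between -0.16 and 0.08. With the upper quartile, 449 genes were at least 4-fold lower, the log2 ratio of Cfh was 4.59 and the microglia median 6.04. Without the 10 most abundant genes, 474 genes were lower and Cfh stood at 4.66. Counts of higher genes ran from 757 to 861 over the 5 scalings, against 896. By construction, the number of lower genes followed the filter and the size rule: 1269 with no filter, 59 at a mean of at least 5 CPM, 61 with 1 CPM added, and 142 where the interval bound had to reach 4-fold. With 1 CPM added the microglia median was 6.03. At 2-fold, 2208 genes were higher and 1188 lower, and at 8-fold 568 and 90. Of 248 medians of other lists under alternatives, 230 stayed within the main interval. Of the 18 that moved beyond it, 17 did so by the constant shift of a scaling and 1, toll-like receptors, with 1 CPM added. When random lists were matched on input CPM, 27 of 32 percentiles kept their place below, within or above the central 95% of random lists. The exceptions were border-associated macrophages (84.6), neurons (97.8), astrocytes (3.69), interferon response (95.6) and cell cycle genes (76.9). For members below 1 CPM in the input this matching draws higher genes by construction, since only measured genes are drawn. Between 47 and 49 of the 50 ranked genes were also among those ranked under each of the 5 scalings. No paired analysis was possible because there is 1 library per group, and for the same reason no library could be left out. Depth limits genes of few input counts, whose intervals are wide.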

Other observations

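The gene families in the next paragraphs, and the tests of carry-over of either kind, of tagged ribosomes in 1 further cell type, of low transgene expression and of length and GC content as a whole cause, were chosen after the results were seen. Several immune families, which share members such as Fcer1g, Fcgr3, Siglech, Nlrp3 and Tgfb1 with the fixed lists, were higher in the immunopurified library. All 5 measured Fc receptor genes were at least 2-fold higher, with a median of 49.3-fold, among them the high-affinity receptor Fcgr1 (86.3-fold, 57.9 to 135) and the inhibitory receptor Fcgr2b (32.3-fold). The median was 57.5-fold for 3 Siglec genes, 37.5-fold for 3 Ms4a genes, 10.7-fold for 4 Slfn genes and 9.31-fold for 3 Gimap genes. Members of these families are close copies of each other, and their counts are uncertain. Of 13 caspase and inflammasome genes 11 were at least 2-fold higher and none lower. The adaptor Pycard was 74.9-fold higher (55.5 to 104), Casp8 37.3-fold and Casp1 10.8-fold, and Nlrp1a, with 219 against 0 counts, at least 76.7-fold against a floor of 3 input counts (lower bound of the counting interval 61.9). In the TGF-beta family the ligand Tgfb1 (42.0-fold) and the receptor Tgfbr2 (15.5-fold) were higher, and Tgfb2 and Tgfb3 lay within 2-fold. Of 52 G protein-coupled receptor genes with a Gpr symbol 9 were higher, 3 lower and 40 within 2-fold, and the higher ones included Gpr65 (133-fold, on 1 input count) and Gpr183 (37.1-fold).

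Outside immunity, 17 aminoacyl-tRNA synthetase genes were taken by symbol, 1 or 2 letters before ars, so synthetase genes with other symbols were not covered. Of the 17, 5 were at least 2-fold higher and 12 within 2-fold. All had a log2 ratio above 0, from 0.41 (Lars) to 1.56 (Vars). Their median was 1.79-fold, at the 99.9 percentile of matched random lists, for a family picked after the results were seen. The lowest of these log2 ratios is larger than the greatest shift of any scaling, 0.29. Neuronal receptor genes sat slightly lower. With total-count scaling all 22 glutamate receptor genes and all 14 GABA-A receptor genes lay within 2-fold, with median log2 ratios of -0.46 and -0.52. Small nucleolar RNA host genes were lower, 9 of 11 by at least 2-fold, with a median log2 ratio of -1.75. The lowest of them, Snhg14 and Snhg11, are also members of the fixed nuclear noncoding and neuron lists. Collagen genes had 15 of 23 within 2-fold, with Col15a1 at 10.9-fold higher.

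Transcripts of other brain cell types stood near a ratio of 1 in the immunopurified library, although microglial genes were 80.7-fold higher. Tagged ribosomes in 1 further cell type would, without carry-over of RNA from untagged cells, leave markers of the unrelated types far below 1. Of 12 lists, 11 had a median whose lower bound lay above a log2 ratio of -1. With carry-over, unrelated types would stay near 1 in either case, so this count cannot decide on a further type. Carry-over of tissue RNA of every kind in proportion to its abundance would leave noncoding RNA near 1 as well. Instead, the nuclear noncoding list had a median log2 ratio of -2.18 (-2.41 to -1.71), with Malat1 at a ratio of 0.136 from 39090 CPM in the input. That list holds nuclear RNA, so it cannot test carry-over limited to cytoplasmic RNA, which stays open. Carry-over of ribosome-bound RNA from untagged cells and low transgene expression in every brain cell type cannot be told apart, since 0 immunopurified libraries from tissue without the transgene were analysed here. The latter is the biological explanation of this pair, and it stays open.

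Ratios of genes below 4-fold also had a spread of their own. Noncoding RNA left behind by the ribosome purification is a candidate explanation for its lower end: the median log2 ratio of 135 lincRNA genes was -1.10 (-1.30 to -1.01), a difference of -1.23 from the protein-coding median of 0.13. Among 12617 protein-coding genes the log2 ratio had a Spearman rho of -0.18 with transcript length and of 0.18 with GC content, too small to name either as a source and too large to exclude it. Removing both left 94.02% of the variance (SD 0.683 before and 0.662 after), which argues against them as the whole cause. Differences between microglial and tissue expression stay open as an untested biological explanation.

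Rpl10a, whose tagged form was used for the purification, was not higher (ratio 0.712) and had only 2.91 and 4.08 CPM. Reads shared with pseudogenes left out of the counts may explain its low level in both libraries: 100% of the 602 words of 50 bases in its coding sequence also occur in transcripts of 5 pseudogenes, against 1.68% of the words that touch an untranslated part. The read length is not given in the sources used here, and longer reads would be shared less. Whether the transgene itself was counted under Rpl10a or Cfh was not tested.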
